A study of Mus musculus with 15 samples.

How the data were processed

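Small RNA sequencing libraries had been made from the hypothalamus of female mice of the inbred strain C57BL/6JOlaHsd at 3 ages. These were postnatal day 14 (PND14, week 2, before puberty), PND35 (week 5, during puberty) and PND56 (week 8, after puberty), with 5 libraries per age and 15 in all. Per the labels' protocols, total RNA with its small RNAs was isolated with the mirVana miRNA isolation kit and libraries were made with the QIAseq miRNA library kit. The authors deposited 1 table of whole-number counts per mature miRNA and library, not normalized. Per the submitters' processing notes, Trim Galore, Bowtie, DESeq2 and the genome build mm10 were used. The program that counted the reads, the miRNA annotation release and whether the kit's molecular identifiers were used to collapse reads are not given in the sources used here. The counts may therefore be reads or molecules, and intervals from them would cover counting error alone. The deposited counts carry no strand information of their own, so how reads of overlapping hairpins were divided is unknown.

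The table held 1842 miRNAs, of which 169 had no count in any library. Total counts ran from 6722608 in PND14 replicate 2 to 16153673 in PND14 replicate 4. At the smallest total, the 3 counts taken as the detection floor corresponded to 0.446 CPM, counts scaled to 1e+06 per library. The edgeR filter filterByExpr on age, with a minimum count of 10 and a minimum total of 15, kept 704 miRNAs. The 1138 miRNAs left out held 0.0121% to 0.0194% of the counts of a library. The counts of each pair of libraries of 1 age were compared by chi-square to look for a library deposited more than once. The smallest chi-square per degree of freedom was 21.6, so all 15 libraries were kept as separate. The labels do not say whether the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical.

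The labels name replicates 1 to 3 of every age by week and replicates 4 and 5 by plain numbers. These are called the name series here. They may mark rounds of laboratory work, which the labels do not state, and each holds all 3 ages. Counts were scaled by TMM and fitted over all 15 libraries with edgeR's quasi-likelihood model, with age and name series as terms and 11 residual degrees of freedom. Each pair of ages, any difference among ages, and the difference between the change from PND14 to PND35 and that from PND35 to PND56 were tested with edgeR's quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over the 704 miRNAs, and an adjusted p below 0.05 was a call. A miRNA was counted as highest or lowest at PND35 when both intervals were called with opposite signs. Fold changes are log2 of the later over the earlier age. Their standard error (SE) is the size of the log2 fold change divided by the square root of F, and is thus the error implied by the test. Levels are TMM-scaled CPM, as mean ± SD over the 5 libraries of an age. Library totals, miRNAs detected and the shares of the top 1 and top 10 miRNAs were compared by exact two-sided permutation tests, adjusted over 12 tests.

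The design, the tests, the alternatives, the naming rule and the miRNA lists were fixed before the data were examined. The 19 lists were the let-7, miR-30, miR-200, miR-29, miR-15/16, miR-130 with miR-301 and miR-181 families, the miR-17-92 cluster with its paralogs, the Dlk1-Dio3 and Sfmbt2 clusters, miRNAs linked to gonadotropin-releasing hormone (GnRH) neurons or puberty, and markers of neurons, oligodendrocytes, microglia and leukocytes, erythroid cells, vessels, pituitary and sensory cells, choroid plexus and cilia, and muscle. Some lists share members, such as the miR-200 family and miR-132 and miR-212 with the GnRH list. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 19 lists. Fry tests whether the members of a list move on balance in 1 direction and does not compare them with other miRNAs. Each of the 6, 4 and 8 lists that camera called in PND35 against PND14, PND56 against PND35 and PND56 against PND14 was also called by fry in the same direction. The 4, 0 and 4 lists called by fry alone are given with its adjusted p. Calls of members are also given adjusted over the list alone. Named miRNAs were, per comparison and among called ones with a mean of at least 10 CPM at the higher age and the same direction in both name series, the 8 largest increases, the 8 largest decreases and the 5 smallest p-values. From each list the rule added up to 4 members by smallest p and the most abundant member. Other miRNAs named were chosen after their values were seen. They are the members beyond the rule that illustrate a count of 5 or fewer, those called in both intervals, those whose intervals differed and the hairpins with unequal arms.

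The ratio of the 5p to the 3p arm of a hairpin was tested across ages on the log2 CPM of both arms with limma, with a prior count of 2 and the same terms, over the 225 hairpins with both arms tested. Hairpins were placed on the mouse genome mm10 (GRCm38) by name in the GENCODE M21 annotation, which holds a hairpin for 660 of the 704 tested miRNAs (93.8%). Of the tested miRNAs, 67 came from hairpins with another annotated hairpin on the opposite strand. Among tested miRNAs 9 sets of identical count rows, 20 rows in all, could not be told apart, and 2 of 17 pairs of opposite-strand arms had total counts within 1% of each other. One of these pairs was miR-219a-5p and miR-219b-3p and the other miR-126a-5p and miR-126b-3p. Their counts are reported as uncertain, since they probably stem from the same reads. The counts of miR-1b-5p, miR-126b-5p, miR-129b-3p and miR-219b-5p, each opposite to a more abundant arm, are also reported as uncertain. miRNAs named without an arm, such as miR-142b and miR-195b, were not compared in such pairs.

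The procedure was tested on simulated counts with known changes in 200 miRNAs. For PND35 against PND14 it called 44.8%, 82.1% and 98.5% of those changed 1.5, 2 and 4-fold, and for PND56 against PND35 it called 40.3%, 77.6% and 93.9%. For PND56 against PND14 the shares were 50.7%, 82.1% and 98.5%. Of the unchanged miRNAs 1.59%, 1.59% and 1.79% were called. Over 20 simulations without any effect the median number of calls was 0. The simulated counts had no age by name series interaction and the same spread in both name series, unlike these data. The shares called may therefore differ in the data. The arm test recovered 53.3% of 30 hairpins given an arm shift of 1 on the log2 scale. Alternatives tried were DESeq2 and limma-voom, median-ratio (RLE) and total-count scaling, no filter, a filter of 10 CPM in 5 libraries, no name series term, a replicate block, each name series alone, 2 ages alone, removal of the 10 most abundant miRNAs, a fold minimum of 2, and each library left out in turn. Keeping shared rows once, a model with an age by name series interaction, composition tests with ages permuted within each name series, the sign in 1 name series of miRNAs called in the other, and the alternatives for the number called the same way in both intervals were added after seeing the data. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.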

Results

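MicroRNAs (miRNAs), small RNAs that repress the messenger RNAs they pair with, were counted in the hypothalamus, the brain region whose GnRH neurons drive puberty. The libraries came from female mice at PND14, PND35 and PND56, which the labels place before, during and after puberty, with 5 libraries per age. The question set by the series was which miRNAs change around puberty. Total counts per library ran from 6722608 to 16153673, and 1088 to 1275 miRNAs had at least 1 count. miR-9-5p, an abundant miRNA of the neural lineage, took 13.5% of the counts at PND14, 10.5% at PND35 and 9.44% at PND56. The share of the most abundant miRNA of a library was 13.7% ± 1.93 (SD, n = 5) at PND14 and 10.6% ± 0.362 at PND35, with an exact permutation p of 0.00794, the smallest that 5 against 5 allows, and an adjusted p of 0.0952. The number of miRNAs detected was 1211 ± 44.1 at PND14, 1150 ± 20.5 at PND35 and 1123 ± 37.8 at PND56, and none of the 12 composition tests had an adjusted p below 0.05. A single test at the smallest p adjusts to 0.0952, so 1 difference alone could not pass. Within replicates 1 to 3 and within replicates 4 and 5, the number detected differed by −49.3 and −77.5 between PND14 and PND35, by −8.67 and −56.5 between PND35 and PND56, and by −58.0 and −134 between PND14 and PND56. The share of the most abundant miRNA differed by −4.29 and −1.37 percentage points between PND14 and PND35. With ages permuted within each name series, where the smallest exact p is 0.0167, the adjusted p-values were 0.10 to 0.767. Some age differed from another in 273 of the 704 tested miRNAs by edgeR, and in 243 and 448 when replicates 1 to 3 and replicates 4 and 5 were fitted alone.

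The first comparison asked what changed between PND14 and PND35. miR-219a-5p, which promotes the maturation of oligodendrocytes, the myelin-forming cells, rose from 8.29 ± 5.49 CPM (SD, n = 5) at PND14 to 112 ± 50.4 CPM at PND35, a log2 fold change of 3.84 ± 0.33 (SE; adjusted p = 2.88e-07). miR-338-3p, which acts in the same maturation, rose 6.01-fold, from 724 ± 186 to 4368 ± 691 CPM (adjusted p = 8.12e-08). miR-29b-3p, of a family that represses collagen messenger RNAs, rose 4.19-fold (adjusted p = 3.01e-07). In the opposite direction, miR-323-3p, from the imprinted Dlk1-Dio3 region, fell by 2.02 ± 0.12 on the log2 scale, from 4537 ± 584 to 1119 ± 149 CPM (adjusted p = 6.33e-09). miR-449a-5p, known from ciliated cells, fell by 2.06 ± 0.28, from 466 ± 215 to 104 ± 18.0 CPM (adjusted p = 3.43e-05).

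**Figure D1:**
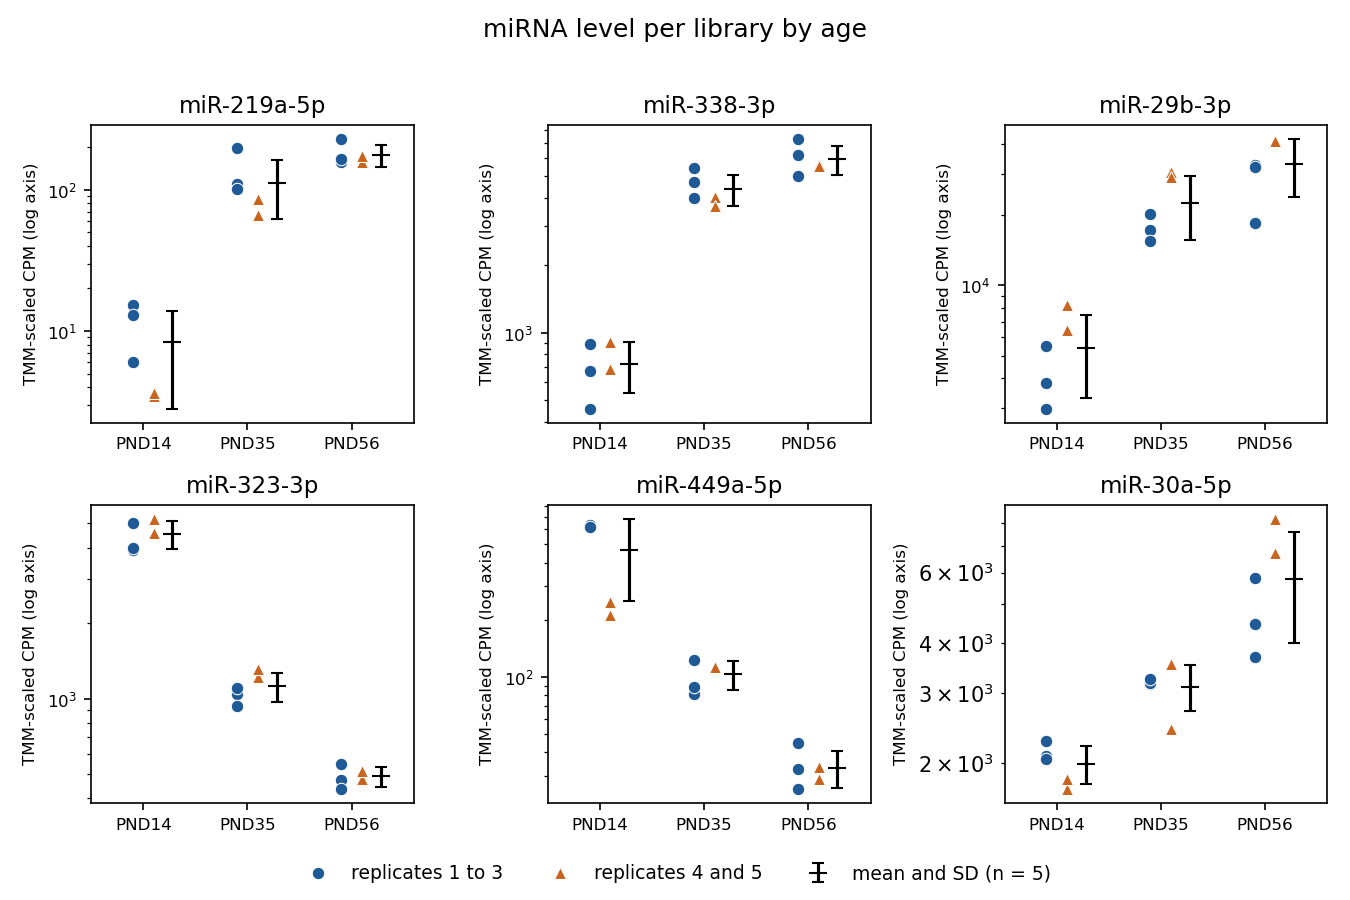
Levels of miR-219a-5p, miR-338-3p, miR-29b-3p, miR-323-3p, miR-449a-5p and miR-30a-5p in each library, in TMM-scaled CPM on a log axis, at PND14, PND35 and PND56. Circles are replicates 1 to 3, triangles are replicates 4 and 5, and the bar gives the mean and SD of 5 libraries; mean miR-219a-5p rose from 8.29 to 112 and 177 CPM while mean miR-323-3p fell from 4537 to 1119 and 489 CPM.

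All 7 tested members of the miR-29 family rose from PND14 to PND35, with a median log2 fold change of 1.78, and all 7 did so adjusted over the list alone. The list moved up by camera (adjusted p = 2.46e-12) and also did so with an estimated correlation (adjusted p = 0.0135). Besides miR-29b-3p at 2.07 ± 0.18, miR-29c-5p rose by 1.78 ± 0.13, miR-29a-3p by 1.36 ± 0.17 and miR-29c-3p by 1.30 ± 0.13. miR-29a and miR-29b-1 lie next to each other between genes on chromosome 6 (31062660 to 31062747 and 31063023 to 31063093, mm10). Of the 8 oligodendrocyte markers 6 rose and 1 fell, also adjusted over the list alone, with a median of 1.83 (camera adjusted p = 2.89e-08, and 0.0326 with an estimated correlation). miR-338 lies in an intron of Aatk on chromosome 11 (120014765 to 120014862). The counts of miR-219a-5p and miR-219b-3p were almost equal and are uncertain as separate values, as are those of miR-219b-5p (2.42 ± 0.25), whose hairpin lies opposite to that of the more abundant miR-219a-2-3p. These miRNAs are among the 6 that rose, so the 6 are not independent markers. With shared rows kept once, which dropped miR-219b-3p, all 18 list calls at the preset correlation were kept. The marker that fell was miR-219a-1-3p, the other arm of a miR-219a hairpin, by 0.94 ± 0.27.

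Of the 91 tested members of the Dlk1-Dio3 cluster, a large imprinted group of miRNAs expressed from the maternal chromosome, 27 fell and 5 rose from PND14 to PND35, and 30 and 6 adjusted over the list alone. Their median was −0.20 (camera adjusted p = 0.00129), and the call was lost with an estimated correlation (adjusted p = 0.147) and in replicates 4 and 5 alone, where the median was −0.23 (adjusted p = 0.116). miR-1188-5p fell by 2.41 ± 0.18, from 73.5 ± 11.4 to 13.8 ± 1.90 CPM, and miR-409-3p fell by 1.62 ± 0.12. miR-370-3p fell by 1.44 ± 0.18, miR-431-5p by 1.39 ± 0.14 and miR-134-5p, which limits dendritic spine growth, by 1.04 ± 0.11. miR-127-3p, the most abundant member, was not called (0.28 ± 0.14, adjusted p = 0.148). The 5 members that rose numbered 3 without PND14 replicate 1 or PND35 replicate 5. They numbered 8 without PND14 replicate 2, and 2 without PND14 replicate 4 or 5 or PND35 replicate 1, 2 or 4. Over the same interval 7 of 21 neuron markers rose and 2 fell, as they did adjusted over the list alone. The neuron median was 0.47 (camera adjusted p = 0.0343, and 0.264 with an estimated correlation). The camera call ended without PND14 replicate 3 (adjusted p = 0.0654), with total-count scaling (0.0553), without the name series term (0.0558) with the interaction model (0.0533) and in replicates 4 and 5 alone (0.154). It also ended with at least 10 CPM in 5 libraries, where the median was 0.22 (adjusted p = 0.271), and without PND14 replicate 1 the markers that rose numbered 4. Among them miR-212-3p, induced by neuronal activity, rose by 1.22 ± 0.15, miR-218-1-3p by 1.58 ± 0.24 and miR-153-3p by 0.90 ± 0.22, while miR-137-5p fell by 0.64 ± 0.15.

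The miR-17-92 cluster with its paralogs, linked to cell proliferation, had 8 of 20 members that fell and 0 that rose from PND14 to PND35, and 10 and 0 adjusted over the list alone. The median was −0.61 (camera adjusted p = 0.00974, and 0.360 with an estimated correlation). The call also ended in replicates 4 and 5 alone (median −0.47, adjusted p = 0.471) and with at least 10 CPM in 5 libraries (0.118). miR-17-3p fell by 0.99 ± 0.24. miR-18b-5p fell by 1.82 ± 0.36, on few counts, from 1.83 ± 0.591 to 0.493 ± 0.213 CPM, where 3 counts make 0.293 to 0.389 CPM in the PND35 libraries. The count of 8 was 3 without PND14 replicate 1, 4 without PND35 replicate 1 or 2, and 5 without PND35 replicate 5. In the family of miR-130 and miR-301, 3 of 7 members fell, also adjusted over the list alone (camera adjusted p = 0.0662, fry adjusted p = 0.0311), miR-130a-3p by 0.96 ± 0.18, miR-130b-3p by 1.24 ± 0.19 and miR-301b-3p by 0.65 ± 0.21. In replicates 4 and 5 alone miR-301b-3p had the opposite sign (0.11) and miR-130a-3p was at −0.30 (adjusted p = 0.0651). The interaction of age with name series, tested over the 3 ages together and not for this interval alone, had an adjusted p of 0.00611 for miR-301b-3p. The call of miR-301b-3p ended without PND14 replicate 1 (adjusted p = 0.0591) or PND35 replicate 1 (0.0544), 2 (0.0824) or 3 (0.0556). Camera called this family down without PND14 replicate 4 or 5, PND35 replicate 4 or 5 or PND56 replicate 3 (adjusted p = 0.00740 to 0.0469), in replicates 1 to 3 alone (1.17e-04) and without a filter (0.00316). In the miR-15/16 family 3 of 14 members rose and 4 fell, and 3 and 6 adjusted over the list alone (camera adjusted p = 0.809, median −0.01, which was above 0 with RLE scaling). miR-195a-5p rose by 0.57 ± 0.11 and miR-503-5p fell by 1.18 ± 0.28. In the miR-181 family 2 of 10 members fell, also adjusted over the list alone (camera adjusted p = 0.572), miR-181a-2-3p by 0.77 ± 0.14 and miR-181c-3p by 0.56 ± 0.13.

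Vessel markers rose in 4 of 8 cases from PND14 to PND35, also adjusted over the list alone (median 0.32, camera adjusted p = 0.0985, fry adjusted p = 0.00801), with the smooth muscle miRNAs miR-145a-5p at 0.90 ± 0.16 and miR-143-3p at 0.47 ± 0.13. Camera called them up without PND14 replicate 3 (adjusted p = 0.0371) and without a filter (4.87e-04). Muscle markers rose in 3 of 7 cases, also adjusted over the list alone (median 0.31, camera adjusted p = 0.0222, and 0.264 with an estimated correlation). The camera call also ended without the name series term (0.0558), in replicates 4 and 5 alone (0.154) and with at least 10 CPM in 5 libraries (0.103). miR-1a-3p rose by 0.62 ± 0.13, miR-133b-3p by 1.04 ± 0.22 and miR-1b-5p, whose hairpin lies on the strand opposite to a miR-1a hairpin so that its counts are uncertain, by 1.55 ± 0.17. In the miR-30 family 5 of 12 members rose, also adjusted over the list alone (median 0.27, camera adjusted p = 0.0985, fry adjusted p = 0.00134). miR-30c-5p rose by 0.90 ± 0.19 and miR-30e-5p by 0.91 ± 0.19. Camera called this family up without PND35 replicate 5 (adjusted p = 0.0473), in replicates 1 to 3 alone (0.0462) and without a filter (0.00184). The count of 5 was 3 without any of PND14 replicates 3, 4 and 5 and PND35 replicates 1, 2 and 3. In the let-7 family 3 of 22 members rose and 1 fell, also adjusted over the list alone (median 0.21, camera adjusted p = 0.346, and 0.0219 without a filter), and 6 rose without PND14 replicate 3. let-7g-5p rose by 0.62 ± 0.15 and let-7c-1-3p fell by 0.56 ± 0.15.

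Choroid plexus and cilia markers went both ways from PND14 to PND35, with 4 of 9 that rose and 2 that fell, also adjusted over the list alone (median 0.36, mean 0.04, camera adjusted p = 0.584). miR-204-5p, of the choroid plexus, rose by 0.86 ± 0.12, while the ciliated-cell miRNAs miR-449a-5p and miR-449c-5p fell by 2.06 ± 0.28 and 0.99 ± 0.25. In miR-449a-5p the log2 fold change was −2.69 in replicates 1 to 3 and −1.02 in replicates 4 and 5. Its interaction of age with name series, tested over the 3 ages together and not for this interval alone, had an adjusted p of 0.00599. The GnRH or puberty list had 4 of 19 members that rose and 1 that fell, also adjusted over the list alone, with a median of −0.09, a mean of 0.14 and camera's direction up (adjusted p = 0.601). Of the 4, miR-212-3p rose by 1.22 ± 0.15, and miR-9-5p fell by 0.34 ± 0.08. The number that rose was 2 without PND14 replicate 1 or 3 or PND35 replicate 1 or 2, and without PND56 replicate 4 the number that fell was 2. The miR-200 family had 0 of 5 members called by edgeR, DESeq2 or limma-voom, also adjusted over the list alone (camera adjusted p = 0.584). Its member with an unadjusted p below 0.05 was miR-429-3p (−0.52 ± 0.22, adjusted p = 0.0936), and 1 member fell without PND56 replicate 4.

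Markers of 3 other cell types were close to the limit of the test. Pituitary and sensory markers fell in 2 of 4 cases, miR-182-5p by 0.55 ± 0.19 and miR-183-5p by 0.77 ± 0.25, also adjusted over the list alone (camera adjusted p = 0.413, fry adjusted p = 0.0314). None of the 2 was called without PND14 replicate 1 or 4 or PND35 replicate 2, 4 or 5, and 1 was called without PND14 replicate 3 or 5, PND35 replicate 3 or PND56 replicate 3 or 4. Of 7 erythroid markers, 6 with distinct counts, miR-451a rose by 0.81 ± 0.26, also adjusted over the list alone (camera adjusted p = 0.584), and 0 were called without PND14 replicate 1 or 5 or PND35 replicate 2 or 3. Without PND14 replicate 3 the call of miR-451a also ended (adjusted p = 0.0570). Of 10 microglia and leukocyte markers miR-142b, not compared with any opposite-strand arm, rose by 0.89 ± 0.32, at a mean of 1.66 ± 0.964 CPM at PND35. Of these markers 0 changed adjusted over the list alone. Their median was 0.00, their mean −0.07 and camera's direction down (adjusted p = 0.809), and with total-count scaling the median had the opposite sign. With 1 library left out 0 were called in 7 cases, PND14 replicates 1, 4 and 5 and PND35 replicates 1, 2, 4 and 5, and 2 fell without PND14 replicate 2 or PND56 replicate 2. Of the 44 tested Sfmbt2 cluster miRNAs, 36 with distinct counts, 1 rose and 2 fell, and 0 adjusted over the list alone (camera adjusted p = 0.785). Camera called this cluster down in replicates 1 to 3 alone (median −0.43, adjusted p = 0.0201) and up in replicates 4 and 5 alone (median 0.83, adjusted p = 0.00421). miR-669k-5p rose by 0.99 ± 0.26 and miR-466i-3p fell by 0.53 ± 0.16. The call of miR-466i-3p ended without PND14 replicate 1 (adjusted p = 0.0605) or 4 (0.0527) and without PND35 replicate 2 (0.0585) or 5 (0.0869). There 3 rose without PND14 replicate 3, and 2 rose without any of PND14 replicates 1, 2, 4 and 5, PND35 replicates 1 and 2 and PND56 replicates 1 to 4. The number that fell was 1 without PND14 replicate 1 or PND35 replicate 2.

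In all, 212 of 704 miRNAs changed from PND14 to PND35, 98 higher and 114 lower, and 268 had an unadjusted p below 0.05. Of the 212, 71 changed at least 2-fold, 31 up and 40 down. Other large changes included miR-135a-1-3p, which fell by 2.26 ± 0.18, miR-3093-3p, which fell by 1.38 ± 0.21, miR-29a-5p, which rose by 1.83 ± 0.31, and miR-344d-3-5p, which rose by 1.55 ± 0.36. The series gave 196 and 356 calls when fitted alone. With the same 704 miRNAs tested in each, 74.7% of the 194 called in replicates 1 to 3 alone had the same sign in replicates 4 and 5, and 68.4% of the 342 called in replicates 4 and 5 alone had it in replicates 1 to 3. Without the name series term 135 were called. For 116 miRNAs (16.5%) the ranges of the 5 and 5 libraries did not overlap, against 0.794% by chance.

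**Figure D2:**
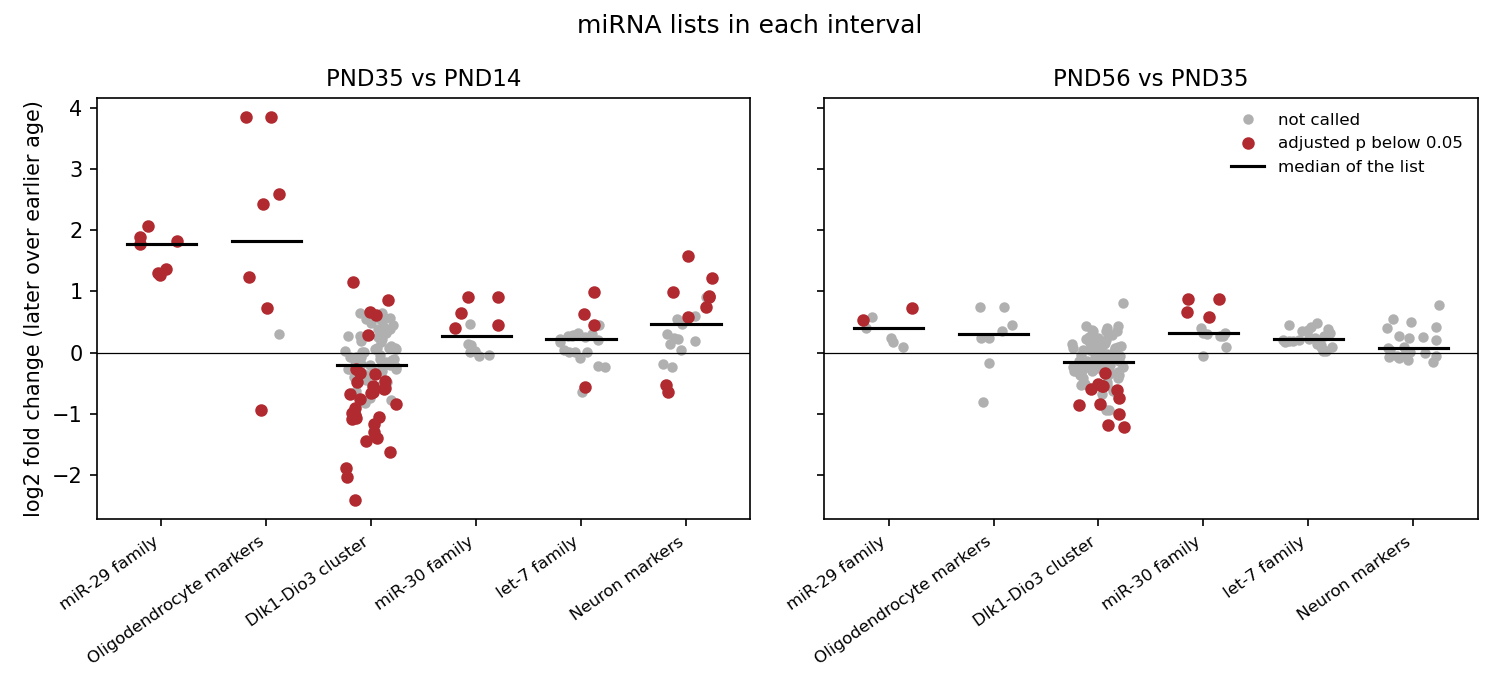
Log2 fold changes (vertical axis) of the tested members of 6 miRNA lists from PND14 to PND35 and from PND35 to PND56. Each point is 1 miRNA, red where its adjusted p is below 0.05, and the line is the median of the list; the miR-29 median was 1.78 in the earlier interval and 0.41 in the later, and the miR-30 median was 0.27 and 0.32.

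The second comparison asked what changed between PND35 and PND56, after the pubertal age. miR-323-3p fell further, by 1.19 ± 0.11 on the log2 scale (adjusted p = 1.15e-05), to 489 ± 43.9 CPM (SD, n = 5). miR-449a-5p fell by 1.67 ± 0.27 (adjusted p = 0.00249), from 104 ± 18.0 to 33.2 ± 7.34 CPM, and miR-412-5p, also of the Dlk1-Dio3 region, fell by 1.01 ± 0.12 (adjusted p = 7.89e-05). miR-30a-5p, of a broadly expressed family, rose 1.84-fold, from 3112 ± 411 to 5775 ± 1784 CPM (adjusted p = 0.0143). miR-30e-5p rose by 0.87 ± 0.19 and miR-30d-5p by 0.67 ± 0.14. Without PND35 replicate 5 the calls of miR-30a-5p (adjusted p = 0.0637), miR-30d-5p (0.0658) and miR-30e-5p (0.0672) ended, and without PND56 replicate 3 those of miR-30d-5p and miR-30e-5p (both 0.0577). With total-count scaling miR-30e-5p was at 0.72 (adjusted p = 0.0556).

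In the Dlk1-Dio3 cluster 12 of 91 members fell and 0 rose from PND35 to PND56, and 14 and 1 adjusted over the list alone. The median was −0.15 (camera adjusted p = 1.06e-05, and 0.0427 with an estimated correlation). miR-1197-3p fell by 1.21 ± 0.26 and miR-409-5p by 0.59 ± 0.10, while miR-127-3p was at 0.29 ± 0.14 (adjusted p = 0.278). The count of 12 was 7 without PND35 replicate 1 or 3, 6 without PND35 replicate 4 or PND56 replicate 3 or 4, and 4 without PND35 replicate 2 or 5. miR-323-3p, miR-412-5p, miR-409-5p and miR-1197-3p were called whichever library was left out. In the miR-30 family 4 of 12 members rose, also adjusted over the list alone (median 0.32, camera adjusted p = 2.90e-05, and 0.0427 with an estimated correlation), 1 without PND56 replicate 3 and 0 without PND35 replicate 5. The let-7 family had 0 of 22 members called by edgeR, DESeq2 or limma-voom, also adjusted over the list alone, and 4 at an unadjusted p below 0.05, but moved up by camera (median 0.22, adjusted p = 0.00249). That call was lost with an estimated correlation (adjusted p = 0.419), without PND56 replicate 2 (adjusted p = 0.0511) and in replicates 4 and 5 alone (median 0.13, adjusted p = 0.238). Its most significant members were let-7f-5p at 0.38 ± 0.13 (adjusted p = 0.153) and let-7b-3p at 0.35 ± 0.15 (adjusted p = 0.230).

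In the miR-29 family 2 of 7 members rose from PND35 to PND56, and 4 adjusted over the list alone (median 0.41, camera adjusted p = 0.00164, and 0.311 with an estimated correlation). miR-29a-3p rose by 0.74 ± 0.17 and miR-29c-3p by 0.53 ± 0.12. The count of 2 was 1 without PND14 replicate 1, 3 or 4 or PND56 replicate 5, and 0 without PND35 replicate 1, 3, 4 or 5 or PND56 replicate 2, 3 or 4. Of the 8 oligodendrocyte markers 0 were called by edgeR, DESeq2 or limma-voom and 4 had an unadjusted p below 0.05, and 3 rose and 1 fell adjusted over the list alone (median 0.30, camera adjusted p = 0.317). In replicates 4 and 5 alone camera called this list up (median 0.73, adjusted p = 0.00463), as it did the neuron markers (0.22, adjusted p = 0.00564). miR-219a-5p was at 0.74 ± 0.29 (adjusted p = 0.207) and miR-338-3p at 0.45 ± 0.17 (adjusted p = 0.205). Neuron markers had 0 of 21 called by the same tools, also adjusted over the list alone, and 4 at an unadjusted p below 0.05 (median 0.07, and −0.10 with total-count scaling, camera adjusted p = 0.239), with miR-129-5p at 0.42 ± 0.15 (adjusted p = 0.153). Of the muscle markers miR-1b-5p alone was called among 7, at 0.61 ± 0.17 (adjusted p = 0.0496), also adjusted over the list alone (median 0.17, camera adjusted p = 0.631), and with 1 library left out it was called without PND14 replicate 2 or PND56 replicate 1 and in none of the other 13 fits. Of 9 choroid plexus and cilia markers 1 fell, miR-449a-5p, and 2 adjusted over the list alone, with a median of 0.19, a mean of −0.11 and camera's direction down (adjusted p = 0.815). In the miR-15/16 family miR-195b alone among 14 rose, by 1.13 ± 0.28, also adjusted over the list alone (median 0.04, camera adjusted p = 0.960). There 0 rose without PND35 replicate 2, 3, 4 or 5 or PND56 replicate 2, 3 or 4, and 2 fell without PND56 replicate 1.

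The other 10 lists had 0 members called from PND35 to PND56 by edgeR, DESeq2 or limma-voom, also adjusted over the list alone, and 6 at an unadjusted p below 0.05. Camera called none of these lists with all libraries. It called erythroid markers down without PND35 replicate 4 (adjusted p = 0.0130), without PND56 replicate 1 (0.0369), in replicates 1 to 3 alone (0.0385) and without a filter (0.0355), and the miR-17-92 cluster down in replicates 1 to 3 alone (median −0.34, adjusted p = 0.00943). Of single members, 1 of the miR-17-92 cluster fell without PND56 replicate 1. Their medians, with camera's adjusted p, were −0.16 for the miR-17-92 cluster (0.189), −0.21 for the family of miR-130 and miR-301 (0.586), −0.09 for the miR-200 family (0.815), −0.30 for erythroid markers (0.123) and 0.09 for vessel markers (0.586). They were −0.02 for the Sfmbt2 cluster (0.815), 0.05 for microglia and leukocyte markers (0.815) and 0.06 for the GnRH or puberty list (0.631), where miR-7a-2-3p was nearest to a call (0.33 ± 0.13, adjusted p = 0.207). The miR-181 family had a median of −0.08 and a mean of 0.00 with camera's direction down (0.821). The pituitary and sensory markers had a median of 0.11 and a mean of 0.03 with camera's direction down (0.960). With total-count scaling the medians of the GnRH, microglia, pituitary, vessel and miR-15/16 lists had the opposite sign.

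In all, 31 miRNAs changed from PND35 to PND56, 12 higher and 19 lower, with 119 at an unadjusted p below 0.05, and 9 changed at least 2-fold, 1 up and 8 down. Others were miR-1983 (−1.07 ± 0.18), miR-6944-3p (−1.01 ± 0.18), whose hairpin lies in an intron of Dbn1, miR-670-3p (−1.02 ± 0.28), miR-3078-5p (−0.92 ± 0.23), miR-129b-3p (0.77 ± 0.14), whose counts are uncertain because its hairpin lies opposite to that of the more abundant miR-129-5p, miR-490-3p (0.68 ± 0.17) and miR-582-3p (0.59 ± 0.16). Of these miR-1983 and miR-6944-3p were called whichever library was left out, and the call of miR-129b-3p ended without PND35 replicate 5 (adjusted p = 0.0563). The other 4 were called in 2 to 9 of the 15 fits without 1 library. The count of 31 was 16, 13, 18, 14 and 7 without PND35 replicates 1 to 5 in turn, and 11, 16 and 19 without PND56 replicates 3, 4 and 5. DESeq2 called 36 and limma-voom 30, and the name series alone gave 7 in replicates 1 to 3 and 121 in replicates 4 and 5. Of these, 7 and 82 (67.8%) had the same sign in the other series. Without the name series term 8 were called, and 52 with the age by name series interaction, which was added after seeing the data. Total-count scaling gave 6 higher and 38 lower calls and moved the median of all miRNAs from 0.04 to −0.12. The ranges of 32 miRNAs (4.55%) did not overlap, against 0.794% by chance.

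The series placed PND35 within puberty, so the shape over the 3 ages was tested directly. The change from PND14 to PND35 differed from that from PND35 to PND56 in 24 miRNAs (119 at an unadjusted p below 0.05), and in 23 of them the earlier change was the larger. The difference was 3.10 ± 0.49 on the log2 scale for miR-219a-5p, 2.14 ± 0.29 for miR-338-3p, 1.54 ± 0.22 for miR-29c-5p, 1.49 ± 0.29 for miR-29b-3p and 1.28 ± 0.26 for miR-212-3p, all rising earlier. It was −2.18 ± 0.32 for miR-1188-5p, −1.66 ± 0.32 for miR-370-3p, −1.41 ± 0.21 for miR-409-3p and −1.10 ± 0.19 for miR-134-5p, which fell earlier. The exception was miR-129b-3p, at −1.03 ± 0.25, with the uncertain counts of a hairpin opposite to a more abundant one. For miR-449a-5p (−0.39), miR-30a-5p (−0.24) and miR-412-5p (0.25) the intervals were not shown to differ. Within the name series 15 and 150 miRNAs differed. DESeq2 gave 41, the fit without the name series term 11 and that with the interaction 71.

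No miRNA was called highest or lowest at PND35 by edgeR, DESeq2 or limma-voom, and 5 had unadjusted p-values below 0.05 in both intervals with opposite signs. Without the filter on low counts edgeR called 1, miR-19a-3p, which fell by 0.73 and then rose by 0.75 (adjusted p = 0.0125 and 0.0337), while replicates 4 and 5 alone gave 16 and the model with the interaction gave 1. In contrast 21 miRNAs were called in both intervals in the same direction, 8 up and 13 down. Those rising included miR-30a-5p, miR-30e-5p, miR-29a-3p and miR-29c-3p, and those falling miR-323-3p, miR-412-5p, miR-449a-5p, miR-487b-3p and miR-1983. The intervals share the PND35 libraries. Independent lists would share 1.67 up and 3.08 down. Simulated data without effects gave 0 such miRNAs, but as at most 2 and 0 were called there in the earlier and the later interval, that value could not have been otherwise. With the PND35 libraries split between the intervals, 2 or 3 to each, 4 to 12 miRNAs were called in the later interval and 4 to 6 of these in both. The count of 21 was 11, 10, 10, 8 and 6 without PND35 replicates 1 to 5 in turn, and 8 and 12 without PND56 replicates 3 and 4. It was 6 without the name series term, 5 in replicates 1 to 3 alone, 53 in replicates 4 and 5 alone and 5 at a 2-fold minimum in both intervals.

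Between the earliest and the latest age, PND14 and PND56, miR-219a-5p rose 24.0-fold to 177 ± 30.8 CPM (SD, n = 5; adjusted p = 2.74e-08) and miR-338-3p 8.22-fold to 5963 ± 881 CPM (adjusted p = 9.63e-09). miR-29b-3p rose by 2.65 ± 0.18 on the log2 scale and miR-30e-5p by 1.78 ± 0.20. miR-449a-5p was 13.3-fold lower (−3.73 ± 0.29, adjusted p = 5.72e-08) and miR-323-3p 9.24-fold lower (−3.21 ± 0.12, adjusted p = 1.08e-11) at PND56. The hairpin of miR-449a lies in an intron of Cdc20b on chromosome 13 (113037534 to 113037624) and that of miR-323 between genes on chromosome 12 (109712508 to 109712593).

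All 7 miR-29 members rose from PND14 to PND56, also adjusted over the list alone (median 2.01, camera adjusted p = 3.11e-11, and 0.0171 with an estimated correlation), with miR-29a-3p at 2.10 ± 0.17, miR-29c-3p at 1.83 ± 0.13 and miR-29c-5p at 2.01 ± 0.14. Of the oligodendrocyte markers 6 of 8 rose and 0 fell, and 6 and 1 adjusted over the list alone (median 2.07, camera adjusted p = 6.50e-06, and 0.0560 with an estimated correlation). miR-219b-5p, with uncertain counts, rose by 2.65 ± 0.25, and 1 marker fell and 5 rose without PND14 replicate 3. In the miR-30 family 8 of 12 rose, also adjusted over the list alone (median 0.63, camera adjusted p = 0.00299, and 0.142 with an estimated correlation), among them miR-30a-5p by 1.52 ± 0.18 and miR-30c-5p by 1.23 ± 0.19. In the let-7 family, which increases as tissues mature, 11 of 22 rose and 1 fell, and 12 and 1 adjusted over the list alone. Its median was 0.39 (camera adjusted p = 0.0348, and 0.505 with an estimated correlation). let-7g-5p rose by 0.94 ± 0.15, let-7d-5p by 0.65 ± 0.10 and let-7f-5p by 0.61 ± 0.14. The let-7 count was 7 without PND14 replicate 4 and 6 without PND14 replicate 5. Its camera call ended without PND14 replicate 1 (adjusted p = 0.0607), PND14 replicate 2 (0.0503) or PND56 replicate 2 (0.0891), and with total-count scaling (0.0757). It also ended in replicates 4 and 5 alone (median 0.21, adjusted p = 0.476), with at least 10 CPM in 5 libraries (0.110) and without the name series term (0.0875).

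In the Dlk1-Dio3 cluster 46 of 91 members fell and 7 rose from PND14 to PND56, and 48 and 8 adjusted over the list alone (median −0.47, camera adjusted p = 6.50e-06, and 0.0495 with an estimated correlation). miR-1188-5p, in an intron of Rian, fell by 2.64 ± 0.19. miR-409-3p, in an intron of Mirg, fell by 1.83 ± 0.12 and miR-412-5p, in an exon of Mirg, by 1.76 ± 0.12. miR-487b-3p fell by 1.87 ± 0.23 and miR-1197-3p by 2.19 ± 0.26. miR-127-3p rose by 0.57 ± 0.14 (adjusted p = 0.00305), with 0.91 in replicates 1 to 3 and 0.10 in replicates 4 and 5. The 89 tested members with an annotated hairpin on chromosome 12 came from 49 hairpins between 109563692 and 109747960 (mm10), a stretch of 184 kb. Over the same ages 11 of 21 neuron markers rose and 1 fell, also adjusted over the list alone (median 0.55, camera adjusted p = 0.0241, and 0.220 with an estimated correlation), and 7 rose without PND14 replicate 4. With at least 10 CPM in 5 libraries the neuron median was 0.35 and the call ended (adjusted p = 0.225). miR-212-3p rose by 1.16 ± 0.15 and miR-153-5p by 1.09 ± 0.19.

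**Figure D3:**
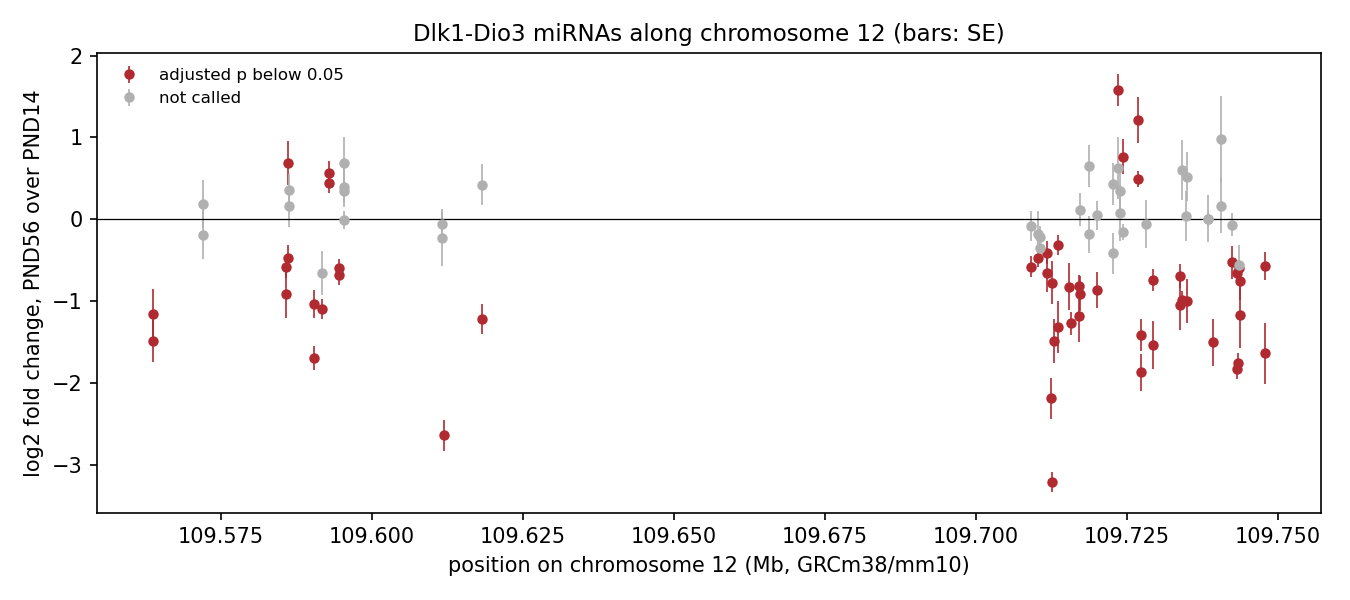
Log2 fold change from PND14 to PND56 (vertical axis, bars are SE) of miRNAs of the Dlk1-Dio3 cluster along chromosome 12 (horizontal axis, Mb, mm10). Each point is 1 tested miRNA at its hairpin; 46 of the 91 tested members fell and 7 rose, with miR-323-3p at −3.21 and miR-127-3p at 0.57.

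The miR-17-92 cluster had 12 of 20 members that fell from PND14 to PND56 and 0 that rose, also adjusted over the list alone (median −0.76, camera adjusted p = 0.00651, and 0.298 with an estimated correlation). The call also ended in replicates 4 and 5 alone (median −0.38, adjusted p = 0.526) and with at least 10 CPM in 5 libraries (0.0808). miR-17-3p fell by 1.31 ± 0.24, and miR-18b-5p, on few counts, by 2.25 ± 0.39 to 0.364 ± 0.169 CPM, where 3 counts make 0.258 to 0.431 CPM in the PND56 libraries. miR-20a-5p fell by 1.15 ± 0.26, with −1.80 in replicates 1 to 3 and −0.06 in replicates 4 and 5. Its interaction adjusted p, over the 3 ages together, was 0.00445. In the family of miR-130 and miR-301, 3 of 7 fell, also adjusted over the list alone (camera adjusted p = 0.0652, fry adjusted p = 0.00791), miR-130a-3p by 1.27 ± 0.18, and 5 fell without PND14 replicate 5. Camera called this family down without PND14 replicate 4 or 5 or PND56 replicate 3, 4 or 5 (adjusted p = 0.0167 to 0.0475), in replicates 1 to 3 alone (9.21e-04), without a filter (0.00411) and with the interaction model (0.0438). In the miR-15/16 family 4 of 14 rose and 6 fell, also adjusted over the list alone, with a median of 0.35, a mean of 0.01 and camera's direction down (adjusted p = 0.964). miR-195b rose by 2.28 ± 0.30 and miR-322-5p fell by 1.13 ± 0.16. In the miR-181 family 2 of 10 fell, also adjusted over the list alone (camera adjusted p = 0.579), miR-181a-2-3p by 0.80 ± 0.14 and miR-181c-3p by 0.65 ± 0.13. There 4 fell without PND14 replicate 3 or PND56 replicate 5, and 1 rose without PND14 replicate 3. Muscle markers rose in 4 of 7 cases, also adjusted over the list alone (median 0.61, camera adjusted p = 0.0348, and 0.298 with an estimated correlation), with miR-1a-3p at 0.94 ± 0.13. The camera call ended without PND14 replicate 1 (adjusted p = 0.0548) or 2 (0.0503), in replicates 1 to 3 alone (0.137), in replicates 4 and 5 alone (0.110), without the name series term (0.101) and with at least 10 CPM in 5 libraries (0.0679). Vessel markers rose in 4 of 8 cases, also adjusted over the list alone (median 0.42, camera adjusted p = 0.0897, fry adjusted p = 0.00152), with miR-145a-5p at 1.17 ± 0.16 and miR-143-3p at 0.66 ± 0.13. Camera called them up without PND14 replicate 3 (adjusted p = 0.0398) and without a filter (4.44e-04). miR-126b-5p, opposite to the far more abundant endothelial miR-126a-3p and so with uncertain counts, rose by 1.05 ± 0.21, while miR-126a-3p itself was at 0.10 ± 0.13.

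Of the choroid plexus and cilia markers 4 of 9 rose and 2 fell from PND14 to PND56, also adjusted over the list alone, with a median of 0.56, a mean of −0.08 and camera's direction up (adjusted p = 0.748). miR-204-5p rose by 1.00 ± 0.12 and miR-449c-5p fell by 1.86 ± 0.27. Of the GnRH or puberty list 5 of 19 rose and 2 fell, also adjusted over the list alone (median 0.01, and of opposite sign with total-count scaling, camera adjusted p = 0.579, fry adjusted p = 0.00436). miR-7a-1-3p, of a family abundant in the hypothalamus, rose by 0.65 ± 0.14 and miR-9-5p fell by 0.33 ± 0.08. Of these, 3 rose without PND14 replicate 4, and 1 fell without PND14 replicate 2 or 3 or PND56 replicate 1, 2, 3 or 5. In the miR-200 family miR-429-3p alone of 5 fell (−0.61 ± 0.22, adjusted p = 0.0363, camera adjusted p = 0.618). None fell adjusted over the list alone, or without PND14 replicate 2 or 3 or PND56 replicate 1, 2, 3 or 5. Of 10 microglia and leukocyte markers 2 rose and miR-142a-3p fell (−0.44 ± 0.13), and 0 and 1 adjusted over the list alone. Their median was −0.11, their mean 0.03 and camera's direction down (adjusted p = 0.981). The number that rose was 0 without PND14 replicate 4 or 5 or PND56 replicate 4, and 1 without PND14 replicate 1 or 3, PND35 replicate 1, 2, 3 or 4 or PND56 replicate 1 or 5, and 2 fell without PND56 replicate 2. Erythroid markers had 0 of 7 called by edgeR, DESeq2 or limma-voom, also adjusted over the list alone, and 0 at an unadjusted p below 0.05 (median −0.26, camera adjusted p = 0.910), and 2 fell without PND56 replicate 1. Pituitary and sensory markers had 0 of 4 called by edgeR or DESeq2 and 1 by limma-voom, 0 adjusted over the list alone and 2 at an unadjusted p below 0.05 (median −0.45, camera adjusted p = 0.579, fry adjusted p = 0.0192), and 1 fell without PND14 replicate 3 or PND56 replicate 1, 4 or 5. In the Sfmbt2 cluster 3 of 44 rose and 2 fell, and 1 and 0 adjusted over the list alone, with a median of −0.07, a mean of 0.02 and camera's direction up (adjusted p = 0.977). miR-669k-5p rose 2.83-fold. In this cluster 5 rose without PND14 replicate 3, and 2 rose and 7 fell without PND14 replicate 5.

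In all, 315 of 704 miRNAs changed from PND14 to PND56, 160 lower and the other 49.2% higher, with 356 at an unadjusted p below 0.05. At least 2-fold, 64 rose and 80 fell. Further large decreases were in miR-135a-1-3p (−2.76 ± 0.19), miR-1983 (−2.35 ± 0.19) and miR-670-5p (−1.90 ± 0.27). The series alone gave 286 and 411 calls. Tested over the same 704 miRNAs, 72.7% of the 286 called in replicates 1 to 3 alone and 70.0% of the 404 called in replicates 4 and 5 alone had the same sign in the other series. Total-count scaling gave 105 higher and 204 lower calls and moved the median of all miRNAs from −0.01 to −0.19. The ranges of 142 miRNAs (20.2%) did not overlap, against 0.794% by chance.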

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

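The 3 tests on PND56 replicate 4 below were chosen after its values were seen. In each age the 5 libraries' levels of the 135 miRNAs named by the rule, and 4 measures of composition, were searched for a library far from the other 4, by a gap that chance exceeds in about 1 in 20 groups of 5. Of 417 groups 21 had such a library, about the number that chance gives, though miRNAs of 1 cluster are not independent. In PND56 replicate 4, miR-183-5p stood at 72.2 CPM against 16.8 to 22.3 in the other 4 libraries, miR-182-5p at 84.3 against 38.0 to 49.5 and miR-96-5p at 63.6 against 18.8 to 28.0. These 3 miRNAs come from 1 cluster known from sensory cells. In the same library miR-200b-3p was at 103 CPM against 33.1 to 41.9, miR-429-3p at 73.8 against at most 36.2 and miR-200c-3p at 31.8 against 18.7 to 22.3, all of the miR-200 family. Libraries of other ages reached higher levels in 4 of these 6, up to 80.9 CPM for miR-183-5p, 109.9 for miR-182-5p, 50.1 for miR-200c-3p and 75.4 for miR-429-3p. The smallest raw count among these 6 was 242. In that library miR-200a-3p was 1.80 times and miR-141-3p, also of the miR-200 family, 0.981 times the median of the other 4 libraries. miR-375-3p, known from endocrine cells, was 1.33 times the median of the other 4 libraries (SD of their ratios 0.65), and choroid plexus and cilia markers had a median ratio of 1.13 (SD 0.15).

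The other 15 values were spread over 8 libraries. At PND14, miR-144-5p was at 56.5 CPM in replicate 4 (others 23.4 to 32.5), and in replicate 3 miR-181b-1-3p was at 10.4 CPM and miR-9-5p at 140896 CPM. At PND35, replicate 4 held miR-146b-5p at 466 CPM, miR-181b-1-3p at 13.4 and miR-3078-5p at 16.6, replicate 1 held miR-18b-5p at 0.124 CPM, below the 0.389 CPM that 3 counts make in that library, and replicate 2 held miR-30b-5p at 907 CPM. At PND56, replicate 3 held miR-219a-5p and miR-219b-3p, whose counts are almost equal and uncertain as separate values, at 230.3 and 230.4 CPM (others 157 to 173). Replicate 2 held miR-20a-5p at 210 CPM, below the 257 to 272 of the others, miR-29a-5p at 29.6 and miR-669k-5p at 6.78. Replicate 1 held miR-301a-5p at 13.0 and miR-503-5p at 129 CPM (others 21.7 to 42.2).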

How the results depend on the processing

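Keeping shared count rows once, the model with an age by name series interaction, the composition tests within each name series, the sign in 1 name series of miRNAs called in the other and the alternatives for miRNAs called the same way in both intervals were tests chosen after seeing the data. The naming rule picked miRNAs from these data, many for a small p-value, a large change or the same direction in both name series. The shares of their calls that were kept therefore need not hold for all calls. Of 154 calls of named miRNAs, the direction and the call were kept in 151 with DESeq2, 152 with limma-voom, 152 with RLE scaling, 140 with total-count scaling, 132 without a filter, 138 with the replicate block and 115 without the name series term. They were kept in 119 of 152 in replicates 1 to 3 and 131 in replicates 4 and 5 alone, 79 at a 2-fold minimum, and 2127 of 2310 comparisons with 1 library left out. Of 18 list calls, 18 were kept with RLE scaling, 16 with total-count scaling, 14 without the name series term, 17 in replicates 1 to 3, 10 in replicates 4 and 5, 11 with at least 10 CPM in 5 libraries, 6 with an estimated correlation, and 263 of 270 with 1 library left out. By depth, 3 counts corresponded to 0.186 to 0.446 CPM in a library. In simulated counts with the totals and library numbers of these data and 1 spread per miRNA for both name series, 40.3% of the 67 miRNAs changed 1.5-fold were called for PND56 against PND35. How much of this is due to depth was not separated, and no age by name series interaction was simulated.

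With DESeq2 the intervals differed in 41 miRNAs. Without a filter 1 miRNA was highest or lowest at PND35. Without the name series term 135 miRNAs changed from PND14 to PND35, 8 from PND35 to PND56, the intervals differed in 11, and 6 were called the same way in both. In replicates 1 to 3 alone, 7 changed from PND35 to PND56, 5 the same way in both intervals, the intervals differed in 15, and the Sfmbt2 cluster's median from PND14 to PND35 was reversed to −0.43. In replicates 4 and 5 alone, the counts were 356 from PND14 to PND35, 121 from PND35 to PND56, 448 with any age difference, 150 for the intervals, 53 the same way in both and 16 for PND35 highest or lowest. There miR-301a-3p (0.70) and miR-301b-3p (0.11) from PND14 to PND35 and miR-181a-5p (0.64) from PND35 to PND56 were reversed. The biological coefficient of variation was 22.5% in replicates 1 to 3 and 12.3% in replicates 4 and 5. A 2-fold minimum gave 71, 9 and 1.4e+02 (64 up and 80 down) changed in the 3 comparisons of ages, 1.5e+02 with any age difference and 5 the same way in both intervals, which follows from its construction. With an age by name series interaction in the model, 52 changed from PND35 to PND56, the intervals differed in 71, and 1 was highest or lowest at PND35. For the rest of these the cause was not tested.

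With the replicate block, 181, 11 and 292 miRNAs changed in PND35 against PND14, PND56 against PND35 and PND56 against PND14, and 8 were called the same way in both intervals. With age removed, 13 of 15 pairs of libraries with the same number correlated above 0.1, and the lowest correlation was −0.19. With the name series also removed, the median was −0.15 and 0 libraries correlated best with their own number, so the numbers were not taken to pair the samples. Leaving out 1 library gave 167 to 227 changed from PND14 to PND35, 7 (without PND35 replicate 5) to 39 (without PND56 replicate 1) from PND35 to PND56 and 268 to 318 from PND14 to PND56. It gave 224 to 296 with any age difference, 16 to 35 for the intervals, 6 (without PND35 replicate 5) to 26 (without PND56 replicate 1) the same way in both intervals and 0 for PND35 highest or lowest.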

Other observations

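The tests of list counts with an estimated correlation, of the neuron markers, of the name series for the arms and the Dlk1-Dio3 cluster, and the splits for miRNAs called the same way in both intervals were chosen after the results were seen. The 2 arms of a miRNA hairpin yield separate mature miRNAs, and they did not always change alike with age. Of 225 hairpins with both arms tested, the ratio of the 5p to the 3p arm differed among ages in 47, and between PND14 and PND56 in 49. For miR-323 the log2 ratio rose by 2.40 ± 0.25 (SE, n = 5 per age), since the 3p arm fell by 3.21 and the 5p arm by 0.78, and for miR-409 by 1.17 ± 0.16. For miR-30a the ratio rose by 1.25 ± 0.26, with miR-30a-5p up by 1.52 and miR-30a-3p at 0.23, and for miR-30e by 1.31 ± 0.25. For miR-338 the ratio was at −1.69 ± 0.30, the 3p arm rising by 3.04 and the 5p arm by 1.48. The miR-338 hairpin lies opposite to that of miR-3065, and its 5p arm had 1399 counts over all libraries against 480257 for the 3p arm. Shared reads and few counts are therefore not set aside for this hairpin. Both arms were called in 62 hairpins and went in opposite directions in 4, miR-137, miR-448, miR-540 and miR-7080. In miR-137 the 5p arm fell by 0.73 and the 3p arm rose by 0.29.

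Reads shared with a hairpin on the opposite strand are argued against as the whole source of the unequal arms by the 192 hairpins without such a partner, of which 20.3% had them. Few counts in the minor arm are argued against by the 22.6% among 53 hairpins with both arms at 50 CPM or more. The smaller share of same signs was as low as a dependence on the name series predicts. Of the 93 hairpins called from PND14 to PND56 in replicates 4 and 5 alone, 53 (57.0%) had the same sign in replicates 1 to 3. The 95% interval of this share was 46.3% to 67.2%. Of the 41 called in replicates 1 to 3 alone, 31 (75.6%, interval 59.7% to 87.6%) had it in replicates 4 and 5. Unequal stability of the arms, or a change in which arm is loaded with age, may also account for the pattern and was not tested. Of 100 splits of the 15 libraries 1, the real one, gave as many hairpins (47, highest other 19). The other splits did not keep the name series balanced over ages, so they cannot exclude chance within the series.

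In the Dlk1-Dio3 cluster 27 members fell from PND14 to PND35, 25 with RLE and 28 with total-count scaling. The fall thus did not depend on the choice among these scalings. The median of all miRNAs was −0.025 with TMM, 0.005 with RLE and −0.032 with total counts, so the counts could hardly differ. A bias shared by these scalings was not tested. A lower share of neurons stays open. Neuron markers had a median of 0.47 (SD 0.57, 7 of 21 rose and 2 fell) beside −0.20 for the cluster. Their adjusted p was 7.35e-04 by fry, 0.0343 by camera and 0.264 by camera with an estimated correlation. With at least 10 CPM in 5 libraries the medians were 0.22 (SD 0.53, 18 markers) and −0.29, and camera called no rise (adjusted p = 0.271). The SD is the spread between markers and not the error of their median, so it cannot decide. The markers did not fall on balance, but their rise was not called in every setting. The name series as the cause stays open for single cluster members. Of the 35 that fell in replicates 4 and 5 alone 29 (82.9%) had the same sign in the other series. Of the 24 in replicates 1 to 3 alone 21 (87.5%) had it. Over all miRNAs called these shares were 68.4% and 74.7%. The cluster median was below 0 in both series, −0.24 in replicates 1 to 3 and −0.22 in replicates 4 and 5. A member can thus share its sign without sharing the fall. With replicates 4 and 5 fitted alone the median was −0.23 (camera adjusted p = 0.116). A single shared change of the whole cluster is argued against by the spread of the members, whose SD was 2.95 times their median standard error. Age itself, acting on the processing or decay of single miRNAs, may account for the pattern and was not tested.

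Between the name series 277 miRNAs differed, 140 higher and 137 lower in replicates 4 and 5. Of 100 splits of the libraries into 9 and 6, 1 gave as many (highest other 230, in a split not checked for its overlap with the name series). The effect of age differed between the series in 180 miRNAs (308 at an unadjusted p below 0.05), among them miR-449a-5p, miR-20a-5p and miR-301a-3p. Library depth is argued against by 157 calls after thinning all libraries to the smallest total. The choice of scaling is argued against by 177 calls with RLE scaling and 200 with total counts. Hairpin GC content is argued against by 147 calls after its trend was removed, beside 164 before, among miRNAs with a GC value. How many of the 147 were among the 164 was not counted. The values that 1 outlying library predicts are there, with 28 calls without PND14 replicate 5, though that leaves 1 library of its age and series, 110 without PND14 replicate 2, 93 without PND14 replicate 4 and 275 without PND56 replicate 1. A library or a difference between rounds of work, which the labels do not state, may account for the pattern, and so may an age effect that differed between sets of animals, which was not tested.

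Other splits of the libraries were set against each count, 100 per result, the real one included. As many miRNAs changed as from PND14 to PND35 in 1 split (real 212, highest other 4) and as from PND14 to PND56 in 1 (real 315, highest other 147). As many had any age difference in 1 (real 273, highest other 61). No other split that was run reached these counts. The splits did not keep the name series balanced over ages, so chance within the series is not excluded. As many changed as from PND35 to PND56 in 2 (real 31, highest other 78). There the highest other exceeded the real count and the splits mixed the name series, so chance cannot be excluded. As many were called the same way in both intervals in 1 (real 21, highest other 0). The intervals share the PND35 libraries with opposite sign, so a split seldom gives such calls and their absence cannot exclude chance. The split with 78 put all 4 libraries of replicates 4 and 5 on 1 side, with PND35 replicate 2, and so nearly followed the name series, within which 7 and 121 miRNAs changed, which points to a structure of the samples. The intervals differed in as many miRNAs in 4 splits (real 24, highest other 1.4e+02). The highest other far exceeded the real count and the splits mixed the name series, so chance cannot be excluded. For PND35 highest or lowest the real count was 0, which all 100 splits reach by construction (highest other 15), so they say nothing about chance. Chance could not be excluded for the number of lists that camera called at the preset correlation, with as many in 28 splits for PND35 against PND14 (real 6, highest other 10), 37 for PND56 against PND35 (real 4, highest other 10) and 14 for PND56 against PND14 (real 8, highest other 11). With an estimated correlation 1 split in each comparison gave as many (real 2, 2 and 2, highest other 1, 1 and 0). These counts are small, and some of the lists were near the threshold. Camera's adjusted p was 0.0427 for the Dlk1-Dio3 cluster and the miR-30 family in PND56 against PND35. It was 0.0495 for the Dlk1-Dio3 cluster in PND56 against PND14. Chance is therefore not excluded here either.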
